A study of Mus musculus with 9 samples.

How the data were processed

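Gene expression was measured by 3′-tag RNA sequencing in back skin of wild-type C57BL/6 mice. The 9 libraries fell into 3 groups of 3 by their labels: unstripped skin with control cream, tape-stripped skin with control cream, and tape-stripped skin with a cream holding nano-sized graphene oxide (NGO). Per the labels' protocols, a mouse received 50 µg of NGO in 100 µL of cream, skin was taken 24 h later, RNA was isolated with Trizol, and 500 ng of total RNA went into a Lexogen QuantSeq library. The labels name the unstripped samples as control cream samples, while the protocol places cream on stripped skin alone, so whether cream touched the unstripped skin is open. The replicates are numbered 1 to 3, and nothing in the labels says that they came from separate animals, so p-values measure the spread between these samples.

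The authors deposited 1 table of whole-number counts per gene symbol for each library. Bowtie2, bedtools and the mm10 build are named in the submitters' processing notes, without versions. How reads with several matches, overlapping genes or strand were counted is not given in the sources used here, so near-identical genes (Krt6a and Krt6b, Hba and Hbb copies, Sprr2 and Lce3 members, Skint members) carry that doubt, as do overlapping and antisense genes. Each table held 23282 entries and 23238 unique symbols. The 44 repeat entries of 35 symbols were kept apart, and 22197 symbols (95.5%) matched GENCODE M21, from which the mm10 coordinates were taken. No entry lacked a gene name. Library totals ran from 2019739 to 6303322 counts. A floor of 3 counts over a group corresponded to 0.310 CPM (the scaled counts of edgeR) in unstripped skin, 0.369 CPM in stripped control skin and 0.220 CPM in NGO-treated skin. Folds against a group at 0 were computed against this floor and are written as lower bounds. Such floors, and the intervals of ratios, cover counting error alone.

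Counts were analysed in R 4.3.3. The edgeR 4.0.16 quasi-likelihood test (robust) was fitted to all 9 libraries with group as the factor, TMM factors and the default low-count filter (filterByExpr), which left 13740 genes. All 3 groups shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE), and CPM values use the TMM-scaled library size, as mean ± SD over 3 libraries. The 3 comparisons were stripped control against unstripped skin, NGO-treated against stripped control skin, and NGO-treated against unstripped skin. No test here can be replaced by permutation, since 3 libraries against 3 give no exact two-sided p below 0.1.

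The design, the tests, the alternatives and 31 gene lists (cell types of skin and underlying tissue, epidermal layers, inflammation, stress and metabolism, taken from general knowledge and not from these samples) were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 31 lists, each of which had at least 5 tested members. Camera was repeated with an estimated correlation, and fry tested whether the members of a list moved, on balance, 1 way. Member counts come from the gene test over all genes, and are also given adjusted over the list alone. The genes to name were fixed by a rule: per comparison, the 6 genes with the largest fitted rise and the 6 with the largest fitted fall among called genes with an average log2 CPM of at least 3 and groups that did not overlap, leaving out predicted and clone symbols. To these were added the 3 members with the smallest p from each list that was called or had at least 3 called members, and each tested member of a 12-gene acute inflammation list. All 12 are also members of other lists, so that list repeats their genes and is no separate evidence. Genes outside the rule are said to be chosen after their values were seen.

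A gene was counted as moved back where it was called after stripping and called in the opposite direction with NGO. Since both comparisons use the stripped control libraries, 100 data sets with the stripping effect and no NGO effect were simulated, and 100 with neither effect for the comparisons that share the unstripped libraries. The 3 control libraries were too few to split. A repeat of this simulation with the spread of each group was chosen after the data were seen. The alternatives fixed beforehand were RLE and upper-quartile scaling, no low-count filter, a stricter filter of 20 counts in 3 libraries, DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, a fit of the 2 compared groups, library sizes without muscle, adipocyte, hair and blood genes, a test against a 1.5-fold change (glmTreat), and leaving out each library. For lists they were the estimated correlation, fry, a prior count of 0.5 and lists without shared genes. Alternatives added after the data were seen were leaving out Rn45s (the ribosomal RNA precursor), thinning to equal depth, leaving out genes at 0 in a group, and a skeletal muscle score as a covariate.

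The procedure was tested on simulated data made from the means, depths and spread of these libraries, with 200 genes changed. Of 50 genes per size, 0% were called at a 2-fold change in each comparison. At a 4-fold change 12% were called for stripping, 14% for NGO and 16% for NGO against unstripped skin. At a 16-fold change 50% were called in each. In the 3 comparisons 1, 2 and 2 unchanged genes were called. All 3 lists moved in the simulation were called and no other list was, and 69 of 100 genes moved back by 16-fold were found. The power for small changes was thus low at this spread, and a gene not called is not shown to be unchanged. Ly6g, Flg, Ahsp and Pi3 were not analysed here. Some genes that the naming rule picks are not reported here.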

Results

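Back skin of C57BL/6 mice was profiled 24 h after treatment in 3 states of 3 libraries each: unstripped skin with control cream, skin injured by tape stripping (which peels off the outer layers) with control cream, and stripped skin with a cream of nano-sized graphene oxide (NGO), a carbon nanomaterial. The series title states its subject as the effect of the NGO cream on acute skin inflammation. Total counts were 2794791, 2924281 and 2937738 in the unstripped libraries. They were 2019739, 3835539 and 4053655 in the stripped control libraries and 2997238, 3926762 and 6303322 in the NGO-treated libraries.

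The groups differed in what the libraries held before any single gene was considered. Markers of skeletal muscle, the panniculus layer under mouse skin, took 0.132% ± 0.102 of counts in unstripped skin, 11.2% ± 4.15 in stripped control skin and 4.52% ± 2.26 in NGO-treated skin (SD, n = 3). Basal epidermal markers took 3.66% ± 0.358, 0.326% ± 0.0813 and 2.17% ± 0.423 in the same order. The ribosomal RNA precursor Rn45s took 14.2% ± 1.63, 23.4% ± 1.51 and 15.3% ± 5.82. Genes detected numbered 15605 ± 918, 12999 ± 491 and 14123 ± 271. The stripped control libraries also resembled each other least. The biological coefficient of variation was 0.461 in unstripped, 1.09 in stripped control and 0.830 in NGO-treated skin. Among genes at 10 CPM or more in a pair of replicates, 3.99% to 7.50% were at 0 in 1 of the pair in stripped control skin, against 0.0207% to 0.137% in unstripped and 0.873% to 1.13% in NGO-treated skin. Counting error alone would leave at most 1.67e-07% in any such pair. The labels do not give RNA quality, so whether it caused these zeros stays open. The bounds given below against groups at 0 cover counting error and not this spread between replicates.

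**Figure D1:**
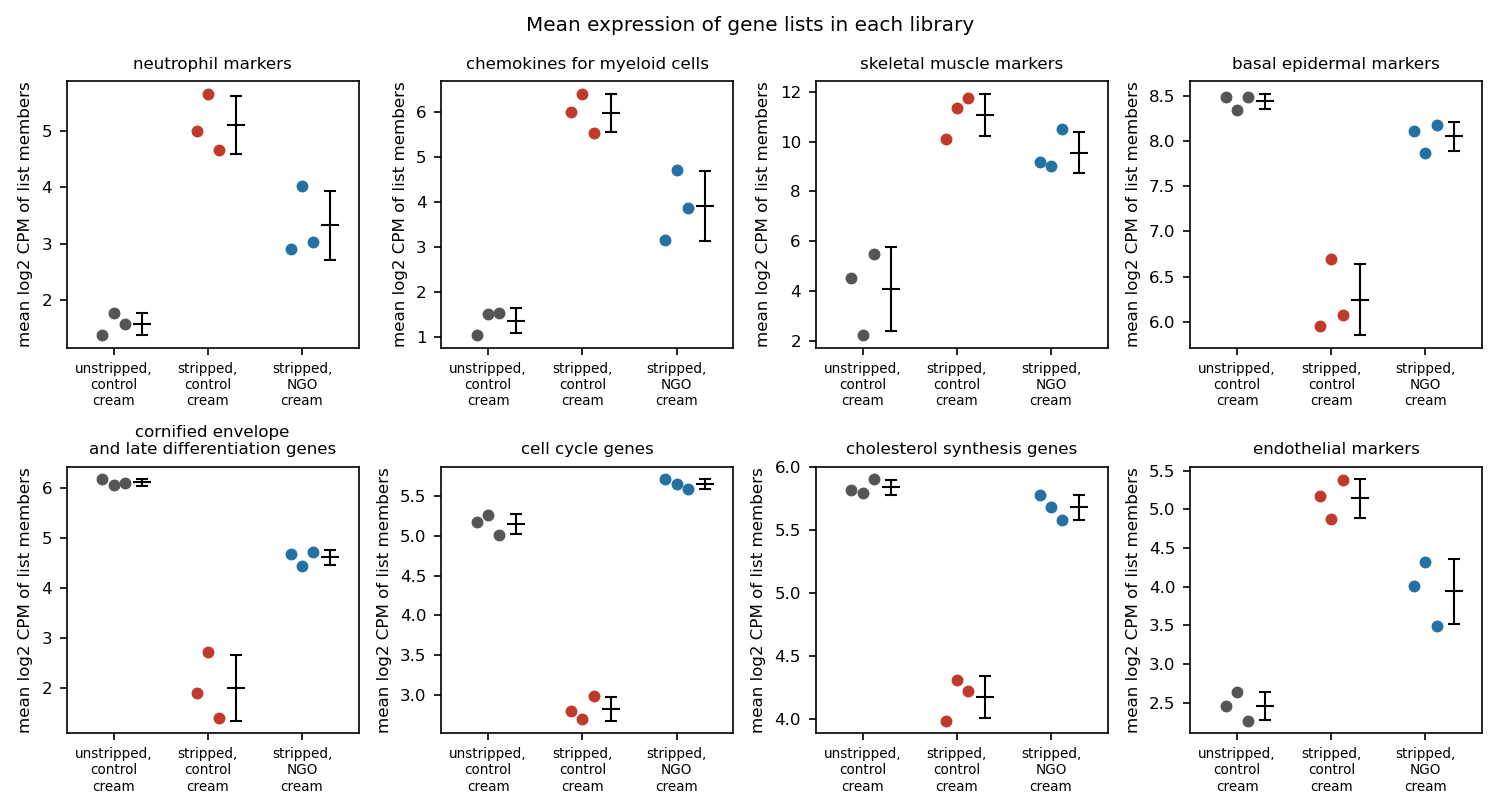
Mean log2 CPM of the members of 8 gene lists (vertical axes) in each library, by group (horizontal axes). Dots are libraries, and the bar beside them is the mean with its SD (n = 3). Neutrophil markers averaged 1.57 in unstripped, 5.11 in stripped control and 3.32 in NGO-treated skin, and cell cycle genes 5.15, 2.82 and 5.65.

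The first comparison set stripped control against unstripped skin. It holds the injury together with the differences in muscle share and in spread between replicates given above, and nothing here separates them. Camera called the neutrophil and myeloid chemokine lists higher (11 of 19 and 10 of 16 members rose), and both held with an estimated correlation (camera adjusted p = 0.0486 and 0.0419). Cxcl2, a chemokine that attracts neutrophils (mm10 chromosome 5, 90903871 to 90905938), went from 1.41 ± 1.08 to 2904 ± 1319 CPM, a log2 fold change of 10.95 ± 0.75 (edgeR adjusted p = 5.78e-06). S100a8 and S100a9, the subunits of calprotectin (chromosome 3, 90668978 to 90670035 and 90692632 to 90695721), rose by 10.05 ± 0.84 and 10.39 ± 0.70. The cytokine gene Il1b (chromosome 2, 129364570 to 129371139) rose by 6.49 ± 0.56, from 6.26 ± 1.48 to 568 ± 310 CPM. Cxcl5 and the acute-phase gene Saa3 had 0 counts in unstripped skin and were at least 1639.9-fold and 1459.5-fold higher. Ccl3, another myeloid chemokine gene, was at least 413-fold higher on the same grounds.

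Of 19 tested neutrophil markers 11 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 5.56e-10), among them Hdc (6.92 ± 0.60), Retnlg (9.59 ± 1.20) and Clec4d (0 counts in unstripped skin, at least 263-fold). Of 16 myeloid chemokine genes 10 rose (11 over the list alone, adjusted p = 4.71e-12), Ccl6 (5.42 ± 0.63) among them, and of 22 wound repair genes 6 rose (8, adjusted p = 3.25e-06), including Hbegf (3.12 ± 0.43) and Timp1 (8.49, edgeR adjusted p = 0.000517). These 3 calls held with an estimated correlation (camera adjusted p = 0.0486, 0.0419 and 0.0419). Of 12 inflammatory cytokine genes 6 rose (7 over the list alone, adjusted p = 9.66e-06), and of 12 genes of the acute inflammation list 5 rose (6, adjusted p = 2.03e-07). Of 20 NF-kB targets 3 rose, Sod2, Sele and Tnfaip2 (5, adjusted p = 0.0084). With an estimated correlation each of these 3 lists had an adjusted p = 0.0503. Besides Il1b the cytokine genes Il19 (from 0 counts, at least 80.5-fold) and Il11 (2.62 ± 0.62) rose, and Il11 was lost without unstripped replicate 1 or 3 (up to edgeR adjusted p = 0.0616). Of 13 antimicrobial genes 5 rose and 1 fell (7 and 2 over the list alone). Of 19 macrophage markers Cd68 (4.33 ± 0.65) and Cd14 (7.92 ± 1.19) rose and 1 marker fell (7 and 1). Both lists had camera adjusted p = 0.000305 and adjusted p = 0.0638 with an estimated correlation. Cytokine and keratin genes of the acute inflammation list that did not pass were Il6 (1.49 ± 1.0001, edgeR adjusted p = 0.379), Tnf (4.68 ± 1.998, 0.144), Ccl2 (1.89 ± 0.88, 0.181), Il33 (-0.78 ± 0.42, 0.256), Tslp (0.00 ± 1.15, 0.998), Krt6a (1.34 ± 0.46, 0.0699) and Krt16 (-0.23 ± 0.45, 0.811). Cxcl1 rose by 6.59 ± 1.03.

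In 5 further called lists few members passed, or members moved both ways. Of 7 mast cell and basophil markers Hdc and Srgn (6.14 ± 0.94) rose (2 over the list alone, camera adjusted p = 0.024, adjusted p = 0.26 with an estimated correlation), and the list's call was lost without stripped control replicate 1 (adjusted p = 0.1001). Mrgprx2, another member of the list, did not pass (edgeR adjusted p = 0.336). Hdc is also in the neutrophil list. Of 29 interferon-stimulated genes Irf7 and Ifit3 were among 3 that rose, and 1 fell (3 and 1 over the list alone, adjusted p = 0.0226, adjusted p = 0.223 with an estimated correlation and 0.178 without stripped control replicate 1). Irf7 was lost without unstripped replicate 2 (edgeR adjusted p = 0.0517) and Ifit3 without unstripped replicate 2 or 3 (up to 0.0774). Of 20 immediate early genes Ier3 (4.36 ± 0.49) and Atf3 (3.07 ± 0.64) rose (2, adjusted p = 0.00801, adjusted p = 0.283 with an estimated correlation), and Gadd45b did not pass (2.85 ± 0.93, edgeR adjusted p = 0.0599). Of 29 NRF2 targets 3 rose, Srxn1, Gpx3 and Slc7a11, and 1 fell (3 and 1, adjusted p = 0.0135, adjusted p = 0.179 with an estimated correlation). Of 26 stress keratin and hyperproliferation genes 6 rose and 4 fell (11 and 4, adjusted p = 0.00535, adjusted p = 0.289 with an estimated correlation). The 3 with the smallest p were Lce3d, up from 0 counts by at least 112-fold, and Sprr2a2 (-3.76 ± 0.61) and Sprr2a3 (-6.15 ± 1.27), cornified envelope genes that fell. Sprr2a3 was lost without unstripped replicate 1 (edgeR adjusted p = 0.0689).

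Markers of tissue below the epidermis rose too. All 22 skeletal muscle markers rose (22 over the list alone, camera adjusted p = 1.6e-24, adjusted p = 0.0638 with an estimated correlation), with a median log2 fold change of 6.78. Actn3 rose by 6.46 ± 0.60, Eno3 by 6.78 ± 0.70 and Casq1 by 8.23 ± 0.90, and Klhl30, Art1 and Fitm1, picked by the rule on fitted fold change, were at 0 in unstripped skin (at least 738-fold, 348-fold and 336-fold). Of 14 endothelial markers 8 rose (10 over the list alone, adjusted p = 7.81e-09) and of 16 adipocyte markers 6 rose (7, adjusted p = 0.000259). Both held with an estimated correlation (camera adjusted p = 0.0218 and 0.043). Examples were Egfl7 (3.61 ± 0.54), Plvap (3.11 ± 0.48), Kdr (3.16 ± 0.52), Cfd (6.28 ± 0.47), Fabp4 (3.58 ± 0.38) and Lpl (3.27 ± 0.37). Of 22 fibroblast and matrix genes 5 rose, including Col3a1 (1.77 ± 0.32) and Dcn (2.59 ± 0.51), and Postn fell by 4.99 (6 and 1 over the list alone, adjusted p = 8.99e-05). Of 8 red blood cell genes 5 rose (5, adjusted p = 2.23e-05), including the globin genes Hba-a1 (3.65 ± 0.42), Hbb-bs (4.43 ± 0.74) and Hbb-b1 (4.41 ± 0.74). Both of these lists had adjusted p = 0.0503 with an estimated correlation. Of 23 glycolysis and hypoxia genes 6 rose and 1 fell (6 and 2, adjusted p = 0.00535, adjusted p = 0.186 with an estimated correlation), led by Hk2 (4.55 ± 0.56), Ldha (2.22 ± 0.30) and Aldoa (3.62 ± 0.56), of which Aldoa is abundant in muscle. The glycolysis call was lost without stripped control replicate 2 (adjusted p = 0.0554).

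Epidermal transcripts fell. Krt15, a basal keratin gene (chromosome 11, 100131758 to 100135928), went from 10891 ± 1128 to 46.4 ± 17.3 CPM (-7.88 ± 0.46, edgeR adjusted p = 2.08e-06), and Krt5 (chromosome 15, 101707070 to 101712898) from 6354 ± 476 to 639 ± 216 CPM (-3.31 ± 0.33). The suprabasal keratin genes Krt1 and Krt10 (chromosome 11, 99385254 to 99389364) fell by 9.20 and 5.66, and the differentiation gene Krtdap by 4.29. Capns2, Alox12e, Sox21, Clca2, Nccrp1 and Ccdc3, picked by the rule on fitted fold change, were at 0 in stripped control skin, at least 656-fold, 503-fold, 342-fold, 290-fold, 268-fold and 246-fold lower. Of 33 cornified envelope genes 19 fell and 0 rose (23 and 0 over the list alone, camera adjusted p = 3.04e-11). Of 20 barrier lipid genes 8 fell (10, adjusted p = 0.000238), including Elovl4 (-2.80 ± 0.36), Aloxe3 (-6.43 ± 1.23) and Cyp4f39 (at 0, at least 92.2-fold lower). Of 32 cell cycle genes 8 fell (9, adjusted p = 8.19e-05), including Top2a (chromosome 11, 98992943 to 99024189; -3.003 ± 0.40), Tpx2 (-7.64 ± 1.16) and Plk1 (-2.70 ± 0.49). Of 25 genes of the cholesterol synthesis list 9 fell (9, adjusted p = 0.00122). Among them were Msmo1 (-2.41 ± 0.39), Cyp51 (-2.41 ± 0.42) and the fatty acid synthase gene Fasn (chromosome 11, 120805846 to 120824547, -3.02 ± 0.41). These 4 calls held with an estimated correlation (camera adjusted p = 0.0419 each). Of 15 basal markers 9 fell, Col17a1 (-3.46 ± 0.44) among them (10, adjusted p = 8.99e-05, adjusted p = 0.0907 with an estimated correlation). Of 16 sebaceous gland genes 5 fell (7, adjusted p = 0.00581), led by Scd1 (-2.77 ± 0.31), Elovl5 (-2.87 ± 0.46) and Krt79 (-4.74 ± 0.86). Of 14 Langerhans and dendritic cell markers 5 fell, led by the antigen presentation genes Cd74 (-4.04 ± 0.56), H2-Ab1 (-3.36 ± 0.57) and H2-Aa (-1.84 ± 0.39) (7 lower and 1 higher over the list alone, adjusted p = 0.00801). Both had adjusted p = 0.0503 with an estimated correlation.

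The 5 lists that camera did not call were T cell markers (adjusted p = 0.17), hair shaft genes (0.061, 0 of 8 members called), melanocyte markers (0.88, 0 of 8), lymphocyte chemokines (0.729) and type 2 immune genes (0.908). Members moved both ways in 3 of them. In the T cell list Icos rose by 2.15 ± 0.41, while Thy1 and Cd2 fell, Cd2 to 0 counts. Thy1 was lost in 5 of the 9 fits that left out 1 library (without unstripped replicate 1 or 2, stripped control replicate 2, or NGO replicate 1 or 3, up to edgeR adjusted p = 0.165) and Cd2 in all 9 (up to 0.116). In the lymphocyte chemokine list Cxcl12 rose by 2.88 ± 0.53 and Ccl27a and Cxcl14, which keratinocytes make, fell by 6.34 and 3.07. In the type 2 list Il4ra rose by 2.39 ± 0.39 and Gata3, also a transcription factor of keratinocytes, fell by 5.55 (Postn is the other member that fell). The counts over these lists alone were 1 higher and 2 lower of 14, 1 and 2 of 7, and 2 and 2 of 9.

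With fry the immediate early (adjusted p = 0.0913), interferon-stimulated (0.217) and stress keratin (0.161) lists lost their call, and without genes shared between lists the mast cell list (0.188). Fry called 4 lists that camera did not, all lower: T cell (0.00807), hair shaft (0.00911), lymphocyte chemokine (0.0145) and type 2 (0.00472).

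In all, 1870 of 13740 genes were called after stripping, 820 higher and 1050 lower (3838 at an unadjusted p under 0.05), and 1854 of them had groups that did not overlap. Over all genes tested, 38.5% had groups that did not overlap, against 10% by chance. More genes were higher than lower with RLE scaling (948 and 931), limma-voom (1392 and 1154) and without unstripped replicate 1 (619 and 569). The count was 3123 with DESeq2, and 1188, 1168 and 1159 without unstripped replicate 1, 2 and 3.

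The second comparison, NGO-treated against stripped control skin, is the one the series title asks about. Camera called the neutrophil and myeloid chemokine lists lower (3 of 19 and 3 of 16 members fell) and the cornified envelope and cell cycle lists higher (12 of 33 and 9 of 32 members rose). With an estimated correlation the first 2 had adjusted p = 0.108, and the last 2 held (camera adjusted p = 0.0495 and 0.01). Cxcl2 went from 2904 ± 1319 to 355 ± 226 CPM (-3.03 ± 0.51, edgeR adjusted p = 0.00571), and it was lower in 3 of 3 NGO-treated libraries than in any stripped control library. Krt5 went from 639 ± 216 to 6216 ± 1085 CPM (3.28 ± 0.33, edgeR adjusted p = 0.000557) and Top2a from 43.4 ± 10.1 to 560 ± 57.0 CPM (3.69 ± 0.41, 0.000676). Markers of muscle were lower in the same direction (median -1.45, 0 of 22 called).

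**Figure D2:**
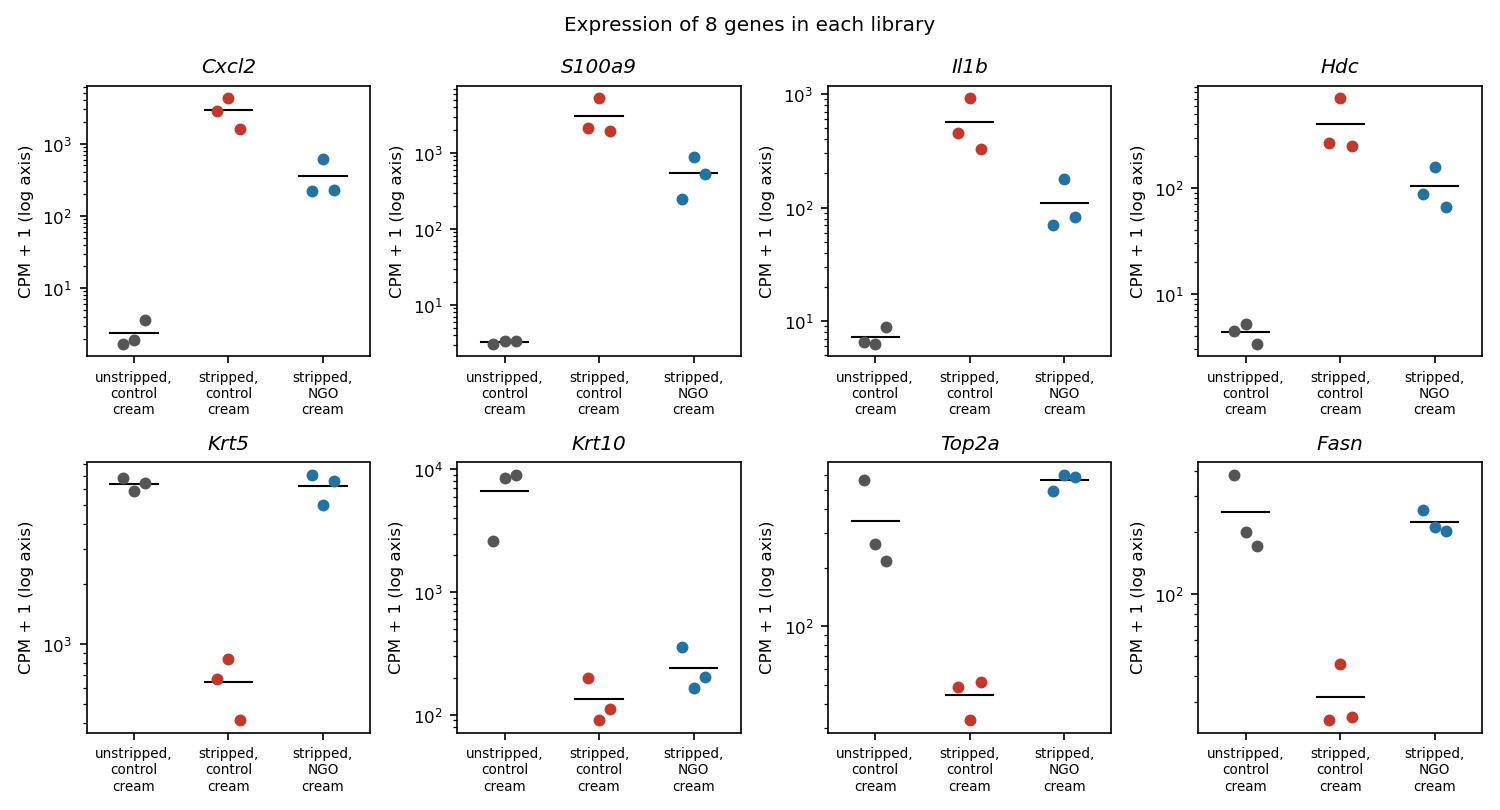
CPM + 1 on a log axis (vertical) of 8 genes in each library, by group (horizontal). Dots are libraries and the line is the group mean (n = 3). Cxcl2, S100a9, Il1b and Hdc were highest in stripped control skin, Krt5, Top2a and Fasn were lowest there, and Krt10 stayed low with NGO.

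Within the inflammation genes, Il1b changed by -2.38 ± 0.46 (edgeR adjusted p = 0.012), S100a9 by -2.50 ± 0.48 (0.012), Saa3 by -2.26 ± 0.41 (0.012), S100a8 by -2.70 ± 0.59 (0.0221), Cxcl1 by -3.32 ± 0.85 (0.0415), Cxcl5 by -2.33 ± 0.57 (0.0417), Mmp8 by -3.24 ± 0.70 (0.0211), Hdc by -1.98 ± 0.47 (0.0303) and Retnlg by -3.23 ± 0.81 (0.0389). Of 19 neutrophil markers 3 fell and 0 rose (6 and 0 adjusted over the list alone). Of 16 myeloid chemokine genes 3 fell (6 over the list alone). Each had camera adjusted p = 4.78e-07 and adjusted p = 0.108 with an estimated correlation. Of 12 acute inflammation genes, each also in another list, 5 fell (7 lower and 3 higher over the list alone, camera adjusted p = 0.0027, adjusted p = 0.207 with an estimated correlation). Members that did not pass were Il6 (-2.73 ± 1.05, edgeR adjusted p = 0.152), Tnf (-2.65 ± 1.79, 0.434), Ccl2 (-2.05 ± 0.88, 0.199), Il33 (1.003 ± 0.42, 0.19), Tslp (0.55 ± 1.15, 0.842), Krt6a (1.58 ± 0.46, 0.0649) and Krt16 (1.18 ± 0.45, 0.153). Of these inflammation genes, Cxcl2 alone passed in all 9 fits that left out 1 library (highest edgeR adjusted p 0.0428). Il1b and S100a9 were lost without NGO replicate 1 or 3 (up to 0.0677 and 0.0527), and Saa3 without NGO replicate 1 or 2 (0.0626). S100a8 was lost without any 1 of the NGO replicates or stripped control replicate 2 (0.0968), Mmp8 without stripped control replicate 1 or NGO replicate 2 or 3 (0.0811), and Hdc without stripped control replicate 2 or NGO replicate 1 or 3 (0.12). Cxcl5 was lost without stripped control replicate 1 or 3 or NGO replicate 1 or 3 (0.144), Retnlg without unstripped replicate 1, stripped control replicate 2, or NGO replicate 1 or 3 (0.121), and Cxcl1 without any 1 of the 6 stripped libraries (0.131). None of them changed sign.

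Camera also called 7 other stress and inflammation lists lower, with 0 to 4 members past the gene test in that direction. Of 20 immediate early genes 4 fell (9 adjusted over the list alone, camera adjusted p = 5.1e-06, adjusted p = 0.143 with an estimated correlation), including the phosphatase gene Dusp1 (-1.88 ± 0.33), Atf3 (-3.15 ± 0.64) and Egr1 (-1.60 ± 0.37). Atf3 was lost without NGO replicate 1 or 2 (up to edgeR adjusted p = 0.0813) and Egr1 without stripped control replicate 2 or any 1 of the NGO replicates (0.106). Of 20 NF-kB targets 2 fell (2 over the list alone, adjusted p = 0.0184, adjusted p = 0.108 with an estimated correlation and 0.0546 without stripped control replicate 2), Nfkbie, an inhibitor of NF-kB (0 counts with NGO, at least 218-fold lower), and Sod2 (-1.10 ± 0.29), which was lost in 8 of the 9 fits, those other than without stripped control replicate 1 (up to 0.15). Bcl3, another target, did not pass (1.93 ± 0.70, edgeR adjusted p = 0.133). Of 12 inflammatory cytokine genes Il1b fell (1, adjusted p = 0.0026). Of 22 wound repair genes Hbegf (-1.56 ± 0.41) and Mmp12 (-2.88 ± 0.76) fell while the matrix gene Tnc rose by 2.21 ± 0.43 (2 lower and 1 higher, adjusted p = 0.0066). Both lists had adjusted p = 0.143 with an estimated correlation, and the wound repair list was lost without stripped control replicate 2 (0.0546). Tnc was lost without NGO replicate 1 (0.0677), Hbegf in 6 of the 9 fits (without unstripped replicate 3, stripped control replicate 2 or 3, or any 1 of the NGO replicates; up to 0.128) and Mmp12 in 8, those other than without unstripped replicate 1 (up to 0.145). Of 29 interferon-stimulated genes 0 fell and 1 rose, against the direction of the list (1 lower and 1 higher over the list alone, adjusted p = 0.00383, adjusted p = 0.181 with an estimated correlation and 0.112 without stripped control replicate 1). Zbp1 (-1.76 ± 0.48, edgeR adjusted p = 0.0505) and Rsad2 (-1.72 ± 0.71, 0.179) did not pass. Of 13 antimicrobial genes 3 fell (4 lower and 1 higher, adjusted p = 0.0498, adjusted p = 0.313 with an estimated correlation). This call was lost without stripped control replicate 1 or 2 or NGO replicate 2 or 3 (up to 0.195). Of 7 mast cell markers Hdc fell (2, adjusted p = 0.0484, adjusted p = 0.368 with an estimated correlation). This call was lost without stripped control replicate 1 or NGO replicate 1 or 3 (up to 0.138). Srgn (-2.58 ± 0.78, edgeR adjusted p = 0.0722) and Mrgprx2 (-1.22 ± 0.62, 0.279) did not pass.

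Epidermal and lipid genes rose. Of 15 basal markers 8 rose and 0 fell (11 adjusted over the list alone, camera adjusted p = 6.64e-06, adjusted p = 0.108 with an estimated correlation), with Krt15 up by 3.77 ± 0.38, to 632 ± 189 CPM, and Sfn by 2.52 ± 0.36. Of 33 cornified envelope genes 12 rose (18 over the list alone, adjusted p = 2.05e-09), including Krt1 (6.03 ± 0.77), Krtdap (2.24 ± 0.32) and Pla2g2f (from 0 counts, at least 41.1-fold). Of 20 barrier lipid genes 7 rose (10, adjusted p = 0.000589), including Elovl4 (2.49 ± 0.35), Slc27a4 (2.605 ± 0.52) and Cyp4f39 (from 0 counts, at least 90.6-fold). Of 25 genes of the cholesterol synthesis list 7 rose (9, adjusted p = 0.000277), including Msmo1 (2.81 ± 0.39), Cyp51 (2.505 ± 0.43) and the fatty acid synthase gene Fasn (2.86 ± 0.41). Of 16 sebaceous gland genes 5 rose (10 higher and 1 lower, adjusted p = 0.000154), including Scd1 (2.57 ± 0.31) and Fa2h (5.49 ± 1.07). Elovl5, another sebaceous member, rose by 1.90 and was lost without unstripped replicate 2, stripped control replicate 1 or 2, or any 1 of the NGO replicates (up to edgeR adjusted p = 0.0868). Of 32 cell cycle genes 9 rose (18, adjusted p = 2.05e-09), including the mitosis genes Plk1 (3.95 ± 0.52) and Tpx2, whose pooled count ratio was 293 (95% interval 52.4 to 11614.9). With an estimated correlation the cell cycle list held (camera adjusted p = 0.01). The cornified envelope and barrier lipid lists (0.0495 each) and the cholesterol and sebaceous lists (0.0476 each) held by a narrow margin. The genes named in this paragraph other than Elovl5 passed in all 9 fits that left out 1 library. Of these, Fa2h, Pla2g2f and Slc27a4 were lost with limma-voom (limma adjusted p = 0.0775, 0.0595 and 0.0544), with the 6 stripped libraries alone (edgeR adjusted p = 0.074, 0.123 and 0.0559) and with the muscle covariate (0.162, 0.164 and 0.0834). With the muscle covariate Krtdap (0.062), Msmo1 (0.0626) and Cyp51 (0.113) were lost too. Spaca6, Aadac, Capns2, Kif2c, Wnt7b and Fbxo5, picked by the rule on fitted fold change, were at 0 in stripped control skin and at least 201-fold, 138-fold, 119-fold, 116-fold, 112-fold and 97.7-fold higher. Capns2 and Wnt7b were lost with limma-voom (limma adjusted p = 0.0635 and 0.168), and Capns2, Wnt7b and Fbxo5 with the muscle covariate (edgeR adjusted p = 0.0977, 0.0692 and 0.0773).

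Of the genes that the rule picked for their fitted fall besides Nfkbie, Cacna1a and Cldn7 had 0 counts with NGO (at least 195-fold and 47.8-fold lower), and Lgr5 and Itch were near 0 (-6.88 ± 1.62 and -6.36 ± 1.55). Of these, Cacna1a was lost without NGO replicate 1 (edgeR adjusted p = 0.0554), Cldn7 without unstripped replicate 1 or 2 or any 1 of the NGO replicates (0.0767), Lgr5 without unstripped replicate 2 or 3, stripped control replicate 3 or any 1 of the NGO replicates (0.0900), and Itch in all 9 fits other than without stripped control replicate 1 or NGO replicate 3 (0.11). Of 14 endothelial markers 0 passed, and the list was lower (0 over the list alone, median -1.10, camera adjusted p = 0.000589, adjusted p = 0.0495 with an estimated correlation), with Vwf at -3.54 ± 1.64, Flt1 at -1.38 ± 0.69 and Kdr at -1.20 ± 0.48. Of 22 muscle markers 0 passed, and the list was lower (0 over the list alone, adjusted p = 6.64e-06, adjusted p = 0.374 with an estimated correlation), with Eno3 at -1.64 ± 0.56, Myoz1 at -1.26 ± 0.48 and Ryr1 at -1.24 ± 0.47. Of 8 red blood cell genes Hba-a1 fell by 1.61 (3 over the list alone, adjusted p = 0.00159, adjusted p = 0.143 with an estimated correlation) and was lost without stripped control replicate 2 or 3 or any 1 of the NGO replicates (up to edgeR adjusted p = 0.126). Of its members, Hbb-bs (-2.06 ± 0.66, 0.0877) and Hbb-b1 (-2.01 ± 0.66, 0.0979) did not pass. The 12 lists not called were macrophage (camera adjusted p = 0.11), T cell (0.607), Langerhans and dendritic (0.607), fibroblast (0.465), adipocyte (0.0743), hair shaft (0.213), melanocyte (0.605), stress keratin (0.213), lymphocyte chemokine (0.78), type 2 (0.256), NRF2 (0.363) and glycolysis (0.136). Among NRF2 targets Srxn1 changed by -2.04 ± 0.49, Prdx1 by 1.27 ± 0.31 and Gsta4 by 2.03 ± 0.51, and each was lost without any 1 of the NGO replicates (up to edgeR adjusted p = 0.108, 0.137 and 0.121). Srxn1 was also lost without stripped control replicate 3 (0.121), and Prdx1 and Gsta4 without unstripped replicate 2 or 3 or stripped control replicate 1 or 2.

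With fry the muscle (adjusted p = 0.201), wound repair (0.0542), antimicrobial (0.168), interferon-stimulated (0.137) and mast cell (0.201) lists lost their call, and the type 2 (0.000704) and Langerhans and dendritic (0.0359) lists were called higher. The antimicrobial and mast cell calls were also lost with RLE scaling (0.0635 and 0.0595), with a prior count of 0.5 (0.0685 and 0.0560) and without genes shared between lists (0.285 and 0.146), and the mast cell call without a filter (0.225).

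In all, 694 genes were called, 532 higher and 162 lower (2919 at an unadjusted p under 0.05), of which 92 of the higher were at 0 in stripped control skin, and 527 were called without genes at 0 in a group. Groups did not overlap for 25.2% of genes tested. The count was 206, 318 and 288 without NGO replicate 1, 2 and 3, 397 and 405 without unstripped replicate 2 and 3, 1936 with DESeq2, 420 with limma-voom, 317 against a 1.5-fold change, 118 when the 6 stripped libraries were fitted alone, and 292 with a muscle score as a covariate, of which 34.2% were higher against 76.7%. With limma-voom 45.0% were higher. The fit of the 6 stripped libraries ended 22 of 50 named calls, Il1b (edgeR adjusted p = 0.0553), S100a9 (0.063) and Krt1 (0.053) among them, without changing a sign. The shared spread of the main fit also drew on the unstripped libraries, which varied less (biological coefficient of variation 0.461) than the 2 groups compared here (1.09 and 0.830). P-values of this comparison may therefore be too small. Whether this or the smaller number of libraries lowered the count to 118 was not tested.

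The third comparison set NGO-treated against unstripped skin. It too holds the differences in muscle share (4.52% against 0.132% of counts) and in spread given above, and nothing here separates them from the injury and the NGO treatment. Of 12 acute inflammation genes 5 were higher and 7 did not pass, and the list had adjusted p = 0.0602 with an estimated correlation. Among genes that passed, S100a9 was higher by 7.89 ± 0.64 (edgeR adjusted p = 7.47e-05), Cxcl2 by 7.92 ± 0.68 (7.47e-05), S100a8 by 7.35 ± 0.77 (0.000259), Il1b by 4.12 ± 0.51 (0.00069), Hdc by 4.95 ± 0.56 (0.000363), Retnlg by 6.36 ± 1.14 (0.00733) and Ccl6 by 5.34 ± 0.63 (0.00048). Cxcl5 and Saa3 were at least 325-fold and 304-fold above unstripped skin. Krt5 did not differ by more than its error (-0.03 ± 0.30, 0.998). The genes Krt10 (-4.81 ± 0.54, 0.000363), Krt15 (-4.11 ± 0.38, 0.000115) and Krtdap (-2.04 ± 0.31, 0.0029) were lower. The wound keratin gene Krt6a (chromosome 15, 101689910 to 101694307) was at 4789 ± 1312 CPM against 634 ± 509 CPM in unstripped and 1604 ± 307 CPM in stripped control skin (2.92 ± 0.48 against unstripped skin, 0.00434).

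Of 19 neutrophil markers 5 were higher (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.55e-06, adjusted p = 0.0997 with an estimated correlation). Of 16 myeloid chemokine genes 7 were higher (9 over the list alone, adjusted p = 8.46e-09), of 13 antimicrobial genes 5 (5, adjusted p = 6.08e-06), of 12 acute inflammation genes 5 (6, adjusted p = 4.45e-08) and of 22 wound repair genes 3, Tnc (3.37 ± 0.45) and Timp1 (6.25 ± 1.20) among them (7, adjusted p = 0.000351). Each of these 4 lists had adjusted p = 0.0602 with an estimated correlation. Of 12 inflammatory cytokine genes Il1b, Il24 and Il19 were higher (3, adjusted p = 0.000449, adjusted p = 0.0997 with an estimated correlation). Il24 was lost without any 1 of the unstripped or NGO replicates (up to edgeR adjusted p = 0.164), and Il19 in 7 of the 9 fits, those other than without stripped control replicate 1 or NGO replicate 1 (0.159). Of 19 macrophage markers Cd14 was higher (2, adjusted p = 0.000631, adjusted p = 0.0997 with an estimated correlation), lost without unstripped replicate 1 or 2 or NGO replicate 2 (up to edgeR adjusted p = 0.159). Of its members, Cd68 (2.38 ± 0.60, 0.0578) and C1qc (3.81 ± 1.43, 0.269) did not pass. Of 26 stress keratin genes 5 were higher (12 higher and 1 lower, adjusted p = 1.43e-06, adjusted p = 0.13 with an estimated correlation), including Krt6b (2.33 ± 0.40) and Lce3c (from 0 counts, at least 103.5-fold), which was lost without NGO replicate 2 (edgeR adjusted p = 0.0563). Of the inflammation list, Il6 (-1.24 ± 1.002, edgeR adjusted p = 0.799), Tnf (2.03 ± 1.81, 0.839), Cxcl1 (3.27 ± 0.93, 0.107), Ccl2 (-0.16 ± 0.86, 0.995), Il33 (0.22 ± 0.42, 0.9754), Tslp (0.54 ± 1.15, 0.977) and Krt16 (0.95 ± 0.45, 0.449) did not pass.

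Of 22 muscle markers 21 were higher (22 adjusted over the list alone, camera adjusted p = 2.8e-32), of 16 adipocyte markers 5 (5 higher and 1 lower, adjusted p = 0.000288), of 14 endothelial markers 2 (5, adjusted p = 3.67e-06) and of 22 fibroblast genes 4 (5, adjusted p = 3.3e-06). Examples were Actn3 (5.399 ± 0.57), Casq1 (6.93 ± 0.86), Eno3 (5.14 ± 0.66), Cfd (5.55 ± 0.45), Fabp4 (3.66 ± 0.38), Plin4 (2.73 ± 0.45), Plvap (2.79 ± 0.47), Egfl7 (2.98 ± 0.53) and Dcn (2.96 ± 0.51), while Kdr did not pass (1.96 ± 0.50, edgeR adjusted p = 0.0614). Col3a1 (1.63 ± 0.31) was lost without unstripped replicate 2 or 3 or NGO replicate 2 (up to 0.0735), and Sparc (1.81 ± 0.36) without unstripped replicate 2 or 3 or NGO replicate 3 (0.0905). Of 32 cell cycle genes 0 passed, and the list was higher (0 over the list alone, median 0.43, adjusted p = 0.0118), with Plk1 at 1.2 ± 0.46, Mcm3 at 0.97 ± 0.45 and Rrm2 at 1.77 ± 0.92. Of 33 cornified envelope genes 5 were lower (9 over the list alone, adjusted p = 8.67e-07), with Krt1 at -3.18 ± 0.59, which was lost without NGO replicate 2 (edgeR adjusted p = 0.0664). Of 14 Langerhans and dendritic cell markers 0 passed and 4 were lower over the list alone (adjusted p = 0.000381), with Cst3 at -1.29 ± 0.33, Cd74 at -1.75 ± 0.50 and H2-Aa at -1.17 ± 0.38. Each list of this paragraph so far had adjusted p = 0.0602 with an estimated correlation. Of 8 red blood cell genes Hba-a1 was higher (3, adjusted p = 0.00114, adjusted p = 0.13 with an estimated correlation), lost without unstripped replicate 2 or 3 or NGO replicate 2 (up to edgeR adjusted p = 0.0714). Of its members, Hbb-b1 (2.40 ± 0.69, 0.111) and Hbb-bs (2.37 ± 0.68, 0.112) did not pass. Of 29 NRF2 targets Gsta4 (3.46 ± 0.54), a detoxification enzyme gene, and Gpx3 (4.77 ± 0.97) were higher (3, adjusted p = 0.0192, adjusted p = 0.226 with an estimated correlation). This list was lost without NGO replicate 2 (0.0552) and Gpx3 without unstripped replicate 1 or 3 or NGO replicate 3 (up to edgeR adjusted p = 0.0927), while Srxn1 did not pass (1.87 ± 0.50, 0.0726). Of 23 glycolysis genes 3 were higher (3, adjusted p = 0.019, adjusted p = 0.296 with an estimated correlation), led by Hk2 (3.11 ± 0.53). This list was lost without unstripped replicate 2 or 3 or NGO replicate 1 or 3 (up to 0.165). Ldha (1.49 ± 0.29) was lost without unstripped replicate 2 or 3 or NGO replicate 2 or 3 (up to edgeR adjusted p = 0.0986), and Aldoa (2.39 ± 0.53) without unstripped replicate 2 or 3 or NGO replicate 3 (0.162). The 13 lists not called were T cell (camera adjusted p = 0.23), mast cell (0.218), sebaceous (0.426), hair shaft (0.274), melanocyte (0.66), basal (0.561), barrier lipid (0.23), lymphocyte chemokine (0.145), NF-kB (0.536), interferon-stimulated (0.766), type 2 (0.394), immediate early (0.0749) and cholesterol (0.933). With fry the macrophage (adjusted p = 0.0545), red blood cell (0.0595), NRF2 (0.0864) and glycolysis (0.156) lists lost their call.

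The rule picked Cxcl5, Klhl30, Saa3, Art1, Lce3d and Clec4d for their fitted rise, each from 0 counts (at least 308-fold, 180-fold, 110-fold and 107-fold for Klhl30, Art1, Lce3d and Clec4d). For their fitted fall it picked Pyy, Cldn7 and Nfkbie, at 0 counts with NGO (at least 279-fold, 153-fold and 24.0-fold lower), and Skint10, LOC100861978 and Skint4 (-8.35 ± 1.58, -7.84 ± 1.55 and -6.99 ± 1.39). Skint10 and Skint4 belong to a family of near-identical keratinocyte genes. Pyy was lost without unstripped replicate 1 (edgeR adjusted p = 0.128), Lce3d without unstripped replicate 1 or NGO replicate 2 (0.0571), Nfkbie without NGO replicate 2 or 3 (0.0727), Skint10 and LOC100861978 without NGO replicate 2 or 3 or unstripped replicate 2 or 3, and Skint10 also without unstripped replicate 1 (0.118 and 0.143), and Skint4 without any 1 of the unstripped or NGO replicates (0.168). In all, 345 genes were called, 283 higher and 62 lower (1609 at an unadjusted p under 0.05), and groups did not overlap for 26.2% of genes tested. The count was 804 with DESeq2, 1284 with limma-voom, 602 with the 2 groups alone, 214 without unstripped replicate 2 and 229 without NGO replicate 3. The shared spread of the main fit also drew on the stripped control libraries. These varied more (biological coefficient of variation 1.09) than the 2 groups compared here (0.461 and 0.830). P-values of this comparison may therefore be too large, which was not tested.

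The last comparison counts the genes called after stripping that were called in the opposite direction with NGO. The NGO-treated samples lay between the other groups in their shares of muscle, basal epidermal and Rn45s counts, given above. Samples that differ in tissue or in how strongly they were stripped could give the same pattern, and nothing here separates these from an effect of NGO. Of the 1870 genes 597 (31.9%) were called in the opposite direction with NGO, 465 of them down and then up and 132 up and then down, and 0 were called in the same direction. They were 86.0% of the genes called for NGO. Moved back were 12 of 19 cornified envelope genes that fell, 8 of 9 basal genes, 7 of 8 cell cycle genes, 7 of 9 cholesterol genes, 6 of 8 barrier lipid genes, 5 of 5 acute inflammation genes (each also in another list), 3 of 10 myeloid chemokine genes, 2 of 11 neutrophil markers, 0 of 8 endothelial markers and 0 of 22 muscle markers. Krt15, Krt1 and Krtdap were moved back and still lower than in unstripped skin, while Krt10 was not moved back (0.86 ± 0.47 with NGO, edgeR adjusted p = 0.317). Of the 597 genes 68 were still called against unstripped skin, and at the low power given above the others are not shown to be back at that level. Because of the shared spread, the 597 may also be too high and the 68 too low. The median log2 fold change against unstripped skin was -0.22 for genes down and then up and 0.97 for genes up and then down.

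**Figure D3:**
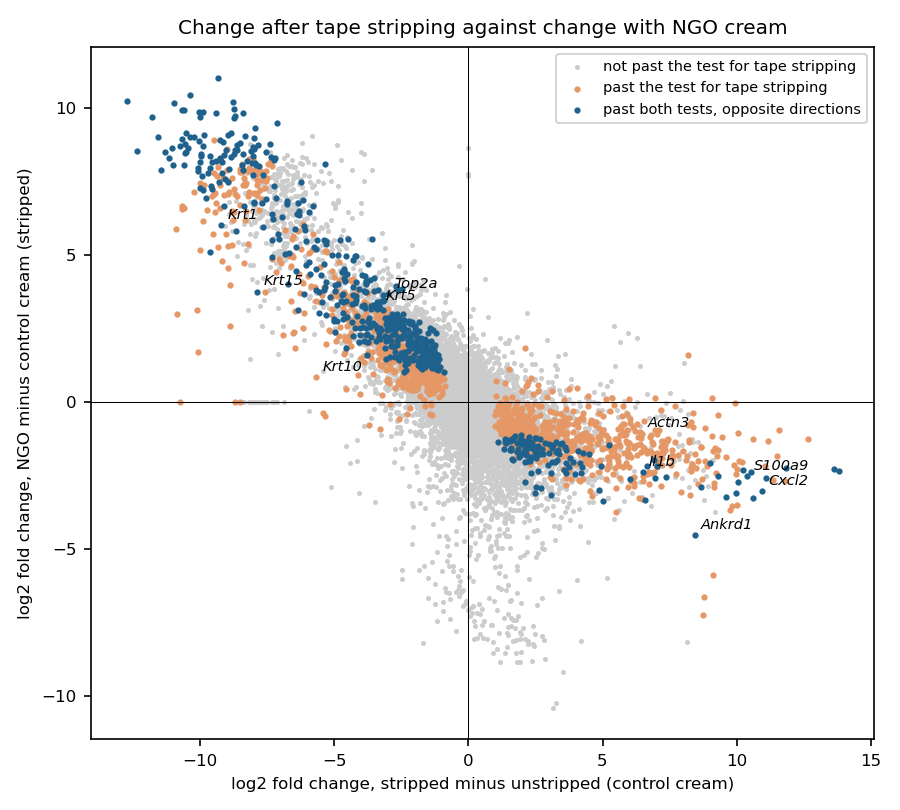
Log2 fold change after stripping (horizontal axis) against log2 fold change with NGO (vertical axis) for the 13740 genes tested, 1 dot per gene. The 597 genes past both tests in opposite directions lie in the upper left (465) and lower right (132), and 0 genes past both tests lie elsewhere. Values of genes at 0 in a group are fitted and are no measure of size.

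Since both changes share the stripped control libraries with opposite sign, chance alone gives opposite directions. Data simulated without an NGO effect called 0.07 genes for NGO on average, so their count of genes moved back (0.01) is near 0 by construction and does not test the reversal. The sign of the NGO change was opposite for 97.8% of the genes called after stripping, against 65.4% ± 0.966 simulated. The covariance of the log2 fold changes over genes was -4.10, against -0.826 ± 0.0370 (SD over 100 simulations), a difference of -3.28. With the spread of each group in the simulation, the covariance was -2.18 ± 0.0648, the difference -1.92 and the share of opposite signs 77.1% ± 1.99. The simulations called 2549 and 3215 genes after stripping on average, against the 1870 observed, so their shares of opposite signs rest on other gene sets. The observed covariance was -2.28 without genes at 0 in a group, which the simulations kept. It was -6.10, -6.38 and -6.60 without stripped control replicate 1, 2 and 3. These 3 fits repeated the low-count filter and tested 14883, 14639 and 14654 genes. Without a filter and with all libraries the covariance was -5.57, so the 3 values do not isolate the weight of a replicate. No simulation left out a library. Genes at 0 in the stripped control libraries were drawn as 0 in both stripped groups. No simulation left out genes at 0 in a group, so -2.28 has no simulated value to be set against. The 3 control libraries could not be split, so part of the excess may come from sharing them. The stripping genes and the genes different between NGO-treated and unstripped skin shared 325 calls in the same direction and 0 in the opposite, a count that sharing the unstripped libraries favours. Their covariance was 2.34, against 0.826 in data simulated with neither a stripping nor an NGO effect (difference 1.51), an excess that 2 stripped groups would show without any effect of NGO. The number moved back was 1382 with DESeq2, 380 with limma-voom, 284 against a 1.5-fold change, 376, 347 and 351 without unstripped replicate 1, 2 and 3, and 180, 298 and 266 without NGO replicate 1, 2 and 3.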

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

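Leaving out Rn45s, thinning, leaving out genes at 0 in a group and the muscle covariate were chosen after the data were seen, and the other settings before. In every setting, each gene called in a comparison and tested again kept its sign. For 239 gene and comparison pairs named by the rule (191 called), 14 settings other than leaving out a library gave 3124 values: 2918 kept direction and side of the threshold, 122 lost the call, 73 gained one and 11 reversed, 0 of them called. The cause of the following shifts was not tested, except that a larger minimum fold lowers the number of calls by construction. Genes called after stripping were 3123 with DESeq2 and 1159 to 2124 with 1 library left out. Genes called with NGO were 1936 with DESeq2, 420 with limma-voom, 118 with the 2 groups alone, 317 against a 1.5-fold change, 292 with the muscle covariate, and 206 to 929 with 1 library left out. Genes called against unstripped skin were 804 with DESeq2, 1284 with limma-voom, 602 with the 2 groups alone and 214 to 495 with 1 library left out. Genes moved back were 1382, 380 and 284 with DESeq2, limma-voom and a 1.5-fold minimum, and 180 to 802 with 1 library left out. The covariance, -4.10, was -4.15 with RLE scaling, -5.57 without a filter, -3.64 with the stricter filter, -4.68 with DESeq2, -3.51 with limma-voom, -4.42 with the replicate block, -3.52 thinned, -2.28 without genes at 0 in a group, and -6.60 to -4.53 with 1 library left out. Called lists fell from 26, 19 and 18 to 9, 6 and 0 with an estimated correlation, and were 24 to 27, 16 to 20 and 17 to 18 with 1 library left out. Against unstripped skin the smallest adjusted p with an estimated correlation was 0.0602, while fry called 14 lists. The share of higher genes with NGO, 76.7%, was 66.6% with RLE scaling, 58.9% with DESeq2, 45.0% with limma-voom and 34.2% with the muscle covariate. After stripping it was 50.5% with RLE scaling, 54.7% with limma-voom and 52.1% without unstripped replicate 1 against 43.9%, and against unstripped skin 66.2%, 65.0% and 61.8% with DESeq2, limma-voom and the 2 groups alone against 82.0%. The median log2 fold change of all genes shifted after stripping by 0.13 with RLE scaling, DESeq2 and without stripped control replicate 1 and by -0.20 with limma-voom, with NGO by -0.12, -0.12 and -0.10 for the first 3, and against unstripped skin by -0.12 with limma-voom.

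Values that reversed were small and not past the test. Tslp after stripping (-0.0047) was 0.11 with RLE, 0.088 with upper-quartile scaling, 0.040 without a filter, 0.021 with the stricter filter, 0.12 with DESeq2, 0.015 with the 2 groups alone, 0.045 with library sizes without the muscle, adipocyte, hair and blood lists, and 0.00046 without genes at 0 in a group. Leaving out 1 library gave Tslp -0.98 to 0.64 after stripping, -0.41 to 1.51 with NGO and -0.42 to 1.20 against unstripped skin. Krt16 after stripping was 0.12 with limma-voom and -0.54 to 0.40 with 1 library left out. With NGO and the muscle covariate, Myoz1 was 0.053 and Ryr1 0.11. Ccl2 against unstripped skin was -1.48 to 0.35 with 1 library left out. The replicate numbers gave no clear sign of pairing, which does not exclude it. Of 9 same-numbered pairs 0 correlated over 0.1 in their deviations from the group means (-0.057 to 0.086, against -0.135 to 0.067 for other pairs). Of 9 libraries 1 correlated best with its own number. The replicate block gave 1650, 559 and 313 genes, 489 moved back, and 27, 19 and 18 lists. With NGO the block ended 10 calls of named genes, Cxcl1 (0.055) among them.

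Each comparison of 3 libraries against 3 has 10 splits, so the share of splits as large as the real one cannot go below 0.1, and in each case 1 split, the real one, was as large. The real counts were 1870, 694 and 345 genes and the highest of the other splits 0 in each comparison. For lists these were 26, 19 and 18 against 15, 12 and 10. For genes moved back they were 597 against 0, and for the covariance -4.10 against -2.16. Every other split mixes libraries of both groups on each side. A real difference between the groups then raises the spread within each side and lowers the count of genes called. The counts of 0 thus do not test the group differences.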

Other observations

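The genes of this paragraph were chosen after their values were seen. Mt1, a metallothionein gene (metallothioneins bind zinc and copper), rose after stripping by 4.16 ± 0.45 (edgeR adjusted p = 7.03e-05) and was still 3.04 ± 0.43 above unstripped skin with NGO (0.00188), its change with NGO being -1.13 ± 0.40 (0.122). Mt2 rose by 2.52 ± 0.34 (0.000265) and changed with NGO by -1.21 ± 0.32 (0.0485). Mt4, the metallothionein of differentiating keratinocytes, fell by 5.43 (0.0052) and its log2 fold change against unstripped skin with NGO was -5.81 ± 1.13 (0.0116). Lgals7, a keratinocyte lectin gene, fell by 3.53 after stripping and rose by 3.80 ± 0.38 with NGO (0.000557). The secreted antimicrobial and acute-phase genes Lcn2, Slpi and Hp rose after stripping by 7.17 ± 0.87, 7.55 ± 0.96 and 5.68 ± 0.45, and their changes with NGO did not pass (-1.53 ± 0.63, -2.13 ± 0.72 and -0.81 ± 0.36; 0.182, 0.107 and 0.218).

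In the same way, Skint4, Skint7, Skint9 and Skint10, from a family of keratinocyte genes with near-identical copies, had 0 counts in the 3 stripped control libraries and were called lower after stripping. Their changes with NGO did not pass (edgeR adjusted p = 0.339, 0.054, 0.102 and 0.628). Myog, a transcription factor of muscle formation, rose by 9.16 ± 1.23 after stripping (0.00028) and changed with NGO by -2.73 ± 0.82 (0.0722). Fosl1, an AP-1 gene of wound edges, rose after stripping by 3.74 ± 0.83 (0.00901) and was 4.19 ± 0.85 above unstripped skin with NGO (0.0152).

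Of the tests in the following paragraphs, the prediction on library sizes for epidermal genes and that on the muscle covariate for neutrophil and chemokine genes were written down before their result was seen. The others were chosen after the values were seen, and the covariate itself was added after the data were seen. Camera called the basal, cornified envelope and barrier lipid lists higher with NGO than in stripped control skin, with 27 of their 68 members called higher. The basal list had adjusted p = 0.108 with an estimated correlation. The 68 members of the basal, cornified envelope and barrier lipid lists had a common median log2 fold change of 2.07. Of these members, 39.7% had a 95% interval that excluded that median (exact binomial interval 28.0% to 52.3%). Without members at 0 in a group it was 17 of 56. A uniform rise in the share of epidermis would leave about 5%, provided that the intervals were wide enough. They rest on the spread shared by all groups (biological coefficient of variation 0.813), below that of stripped control skin (1.09), and may be too narrow. The binomial interval takes the members as independent, although they were measured in the same libraries. The 39.7% thus cannot decide on a uniformly larger share as the whole cause. Samples with unequal gains of the epidermal layers remain possible too. Taking muscle, fat, hair and blood genes out of the library sizes gave 2.07 (SE 0.446), but this setting moved hardly any value and decides nothing. With the muscle score as a covariate the median was 2.43 (SE 0.50), so the rise did not shrink. These SEs are taken over member genes of the same libraries, so they are no error between samples and do not decide on muscle. With this covariate 133 of the 694 genes called with NGO stayed called, and 34.2% of its 292 calls were higher. How much epidermis and muscle each sample held, the quality of the RNA, which the labels do not give, and the NGO treatment all stay open.

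Camera called neutrophil and myeloid chemokine genes lower with NGO (3 of 19 and 3 of 16 members fell; adjusted p = 0.108 for both with an estimated correlation). If the samples simply held less dermis, fat and vessel, these genes would fall as much as the fibroblast, adipocyte and endothelial markers, but the difference of the 2 scores changed by -1.46, against a sum of the group SDs of 1.39, and was below every stripped control library (lowest -0.146) in each NGO-treated one (highest -0.248). With the muscle score as a covariate among the 6 stripped libraries the median log2 fold change of the 35 members was -2.49 (SE 0.647), against -2.13 (SE 0.393) without it. The fall thus did not shrink, and the median stayed below 0 by more than its SE. This SE is taken over member genes of the same libraries, so it is no error between samples and cannot decide on less muscle. With the covariate Hdc (edgeR adjusted p = 0.155), Retnlg (0.0582), Il1b (0.0628) and S100a9 (0.125) lost their call and kept their sign. Of 72 named values with NGO 30 lost the call, 39 stayed as they were, 1 gained one and 2 reversed. The margin of the score difference is small, and its test was chosen after the values were seen. Its reference score also averages 3 scores that moved apart (fibroblast 0.15, adipocyte -0.34, endothelial -1.20). The difference thus cannot decide on less dermis, fat and vessel. The score of red blood cell genes changed by -1.62, near that of neutrophil markers (-1.78). Less muscle, dermis, fat, vessel or blood in the samples, a difference in how strongly they were stripped and an effect of NGO on inflammation remain open.

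Genes that muscle fibres raise under stress or stretch were lower with NGO beyond the muscle markers, a pattern and a gene set picked from these values, so its size may be inflated by the choice. Of 11 such genes (Hspb1, Hspb7, Hspb8, Cryab, Bag3, Flnc, Ankrd1, Ankrd2, Xirp1, Xirp2 and Csrp3, none of them in the muscle list) 11 rose after stripping (median 8.67) and 8 fell with NGO (median -2.43), against 0 of 22 muscle markers (median -1.45), with Ankrd1 at -4.51 ± 0.66 (edgeR adjusted p = 0.00263). The score of these genes minus that of the muscle markers changed by -1.19, against a sum of the group SDs of 0.377. Since the genes were picked for this fall, the values restate the choice and exclude nothing. A smaller share of muscle, a lower stress response of muscle and a difference in how the tissue was stripped or taken all stay open.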
